A study of Mus musculus with 88 samples.

How the data were processed

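The series holds 88 samples of mouse hearts (C57/BL6J). In 11 of them, single cells of the ventricle were sequenced on the ICELL8 platform, a chip of small wells, at E18.5, at P1 to P7, and at P10, P14 and P28. In 19 samples, RNA bound to G3BP1, NCBP2 or PTBP1 was recovered by CLIP (crosslinking and immunoprecipitation) in cardiomyocytes (CM), endothelial cells (EC) and fibroblasts (FB) of the neonatal heart. The other 54 bulk RNA samples and 4 single-cell samples at 5 weeks were not analysed here, so the planned comparison of Ncbp2 overexpression could not be run. Per the labels' protocols, neonatal ventricles were digested with a primary cardiomyocyte isolation kit and pre-plated for 1 h, and adult hearts were perfused with collagenase on a Langendorff apparatus and spun at low speed. In the authors' cell table, names of units carry CM or NCM for P10, P14, P28 and the P7 batch named P7, and neither for E18.5 to P6 and the P7 batch named 7. These names are read here as cells isolated in cardiomyocyte and non-cardiomyocyte fractions (fractionated) or not (unfractionated), a reading that no source used here states, and the pre-plating of neonatal cells also parts the 2 fractions.

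The deposited count table holds read counts per gene and cell, whole numbers with no normalization. Per the submitters' processing notes, time course reads were demultiplexed with bcl2fastq 2.18.0.12, trimmed with cutadapt 1.8.1, aligned to mm10 with STAR 2.5.2b and counted with featureCounts, whose version is not given in the sources used here. The deposited cell table gives counts (reads sequenced, reads in genes and genes detected per cell) and, in percent, the mitochondrial and the assigned share of reads. Filters on cells are not given in the sources used here, and genes of the mitochondrial genome are absent from the count table. Cell types are the authors' annotation, with names kept as written (MP, rMP, GR, ER, PC, SMC, MyoFB, T, B and others). The deposited exon inclusion tables hold, per event and cell, a fraction (PSI) between 0.00012332 and 0.9998767 with no missing value, so they are estimates of a model whose tool is not given in the sources used here. Per event, a median of 89.0% of the CM of a stage carried 1 shared value, and the read depth behind each PSI is unknown. The deposited CLIP files are lists of gene symbols without values. Per the submitters' processing notes, cutadapt 1.8.1 and BWA 0.7.17 came before them, while peak caller, thresholds and the joining of replicates are not given in the sources used here. G3BP1 in CM had 3 CLIP samples and every other list 2.

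Reads were summed per stage and cell type. Each stage is 1 library, so no stage was tested against another. A gene's age trend is its slope on log2 of the postnatal day over the 10 postnatal libraries, in log2 units per doubling of age, fitted with edgeR 4.0.16 (quasi-likelihood, TMM normalization, filterByExpr with a minimum count of 10), and P1 to P28 spans 4.81 doublings. Benjamini-Hochberg adjusted p under 0.05 over all genes of a cell type was the threshold, two-sided. Folds are fitted values at P28 over P1, and levels are counts normalised to library size (CPM), with TMM factors for genes along the age trend. Marker levels per type, means over units and the intervals at E18.5 and P1 use library totals alone. Nothing in the sources used here says that stages, or the 47 units in the cell table (2 to 8 per stage), came from separate animals, so a p measures the scatter of libraries about the line. No paired analysis was possible because no label pairs samples of different stages, while cell types of 1 stage share a library. Types with at least 10 cells in at least 8 postnatal stages were fitted. Differences between types were tested in edgeR as the interaction of type and log2 day, with the stage as block.

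Before the data were examined, gene lists, tests, alternatives and naming rules were fixed. Lists covered adult and fetal sarcomere, calcium and ion handling, oxidative phosphorylation, fatty acid oxidation, glycolysis, cell cycle, imprinted growth genes, fetal Lin28 and Igf2bp genes, extracellular matrix, endothelial maturation, interferon and MHC, dissociation response, spliceosome, SR and hnRNP proteins, muscle splicing regulators, genes with known splicing events in heart, cap binding, stress granule, and markers of 13 cell types. A list of 13 genes encoded by the mitochondrial genome could not be tested, since none is in the count table. The other 32 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated one, Benjamini-Hochberg over the lists of a cell type. The cell type marker lists hold, for example, Tnnt2, Myh6 and Actc1 for cardiomyocytes, Pecam1 and Cdh5 for endothelium, Col1a1 and Dcn for fibroblasts, and Cd3e and Trbc2 for T cells. Named genes are, per cell type, the 8 steepest rising and 8 steepest falling past the threshold with an average log2 CPM of at least 5, without predicted genes, clones, microRNAs and ribosomal protein genes. Up to 4 members per list with the smallest p, Ncbp2, G3bp1 and Ptbp1, the 8 largest called PSI changes per type, the smallest p event per gene of the splicing list, and the 5 largest differences between types in each direction were named too. A gene with a called exon event that meets these rules is not reported here. For CLIP lists, members of fixed lists and, per protein, up to 8 genes found in all 3 types were named by mean CPM. Coordinates are those of GRCm38.p6, build mm10.

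Mean PSI per event, stage and type was fitted with limma on log2 day, weighted by cells, over events in at least 8 postnatal stages. An event was called at adjusted p under 0.05 and a fitted change of at least 0.10 from P1 to P28. CLIP lists were compared with trends and with each other by Fisher's exact test, two-sided, against genes tested in that cell type. They were also set against 10000 random lists matched on expression in 20 bins. Shares of cell types among non-cardiomyocytes were correlated with log2 day by permutation with 100000 resamples, two-sided, and their intervals are exact (Clopper-Pearson) at 95%. E18.5 and P1 are single libraries and were set side by side without a test, with exact Poisson intervals. A list's median was ranked among 10000 random lists, drawn from all tested genes without matching on expression. Intervals cover counting error only. On simulated data the trend test recovered 31.3% of genes with a slope of 0.5 and 100% with a slope of 1, among 200 changed genes, with 4 false calls. It recovered no gene at a slope of 0.25. The test of differences between types recovered 8.96% at a difference of 0.5 and 83.3% at 1. The PSI test recovered 97.0% of simulated events changed by 0.2 and 14.7% of those changed by 0.1, the smallest change that could be called. It also called 5 unchanged events. These shares are not the power in the real PSI, where recovery can be much lower. There Trip4 in CM, with a fitted change of -0.988 ± 0.272, only just passed (adjusted p = 0.0496, limma). Mean PSI in CM also differed between libraries, with 0.445 at P6 and 0.528 at P7. In the simulated counts all genes had the same dispersion, only genes of higher mean CPM changed, and types shared no stage effect. Recovery in the real data can be lower: Postn in CM (slope -1.00 ± 0.30) had an adjusted p of 0.103 (edgeR).

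Alternatives set beforehand were DESeq2 1.42.0 (its test, and its size factors in edgeR), no filter, a minimum count of 50, the unlogged day, stage rank with E18.5, mean CPM per cell in limma, equal numbers of cells, a depth covariate, removal of ribosomal protein genes, each stage left out, an interaction without block, other PSI weights, scales and minimum changes, and other CLIP backgrounds. Alternatives chosen after seeing the data were the P7 batches apart, P1 to P7 with batch 7, P7 to P28 with batch P7, the finer cell names, the level of cardiomyocyte markers as covariate, genes at least as high in EC or FB as in CM, units as samples with the stage as a random block (limma), removal of P6 (lowest assigned share of reads, 68.9%) and P10 (highest mitochondrial share, 27.5%), PSI in cells with at least 10 reads of the gene, and PSI away from the shared value. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.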

Results

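The time course holds 31490 cells of the ventricle from 11 stages, annotated by the authors into 13 types, with reads counted over 37204 genes. The stages hold 3140 cells (E18.5), 3430 (P1), 1848 (P2), 2490 (P3), 3418 (P4), 2890 (P5), 2199 (P6), 5259 (P7), 2471 (P10), 2495 (P14) and 1850 (P28). In mega reads (M), reads counted in genes came to 1203.4 M (E18.5), 1746.9 (P1), 1123.5 (P2), 2186.6 (P3), 1994.4 (P4), 1583.7 (P5), 1170.1 (P6), 3126.1 (P7), 1610.7 (P10), 1479.7 (P14) and 1426.7 (P28). A cell had a median of 403826.5 reads in genes (3002 to 6886286) and of 4012 genes. The median number of genes per cell went from 4401.5 at P1 to 3252 at P28, with the lowest value, 2874, at P14. The mitochondrial share of reads was 10.3% at P1, 27.5% at P10 and 18.9% at P28. Each stage is 1 library, so values of a stage have no replicates, and errors below are standard errors of slopes over 10 stages unless another n is given. The CLIP lists hold between 770 genes (PTBP1 in EC) and 2531 genes (NCBP2 in CM).

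The age trend asks which genes of each cell type change as the heart grows after birth. In CM, Xirp2 rose 126-fold in the fit from P1 to P28, at a slope of 1.45 ± 0.12 (adjusted p = 2.7e-06, edgeR). It encodes an actin-binding protein of the intercalated disc (mm10 chromosome 2, 67446000 to 67526620). Its measured level was 5.26 CPM at P1 and 507 at P28. Tuba8, an alpha-tubulin (chromosome 6, 121210734 to 121226098), rose 83.7-fold with a slope of 1.33 ± 0.13, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (chromosome 7, 45335269 to 45338973), rose 41.4-fold with a slope of 1.12 ± 0.18. H19, an imprinted noncoding RNA (chromosome 7, 142575530 to 142578146), fell from 645 to 2.64 CPM with a slope of -1.67 ± 0.33, and its neighbour Igf2, a fetal growth factor (chromosome 7, 142650768 to 142666816), from 1010 to 12.3 CPM with a slope of -1.28 ± 0.25. Myh7, the myosin heavy chain of the fetal mouse ventricle (chromosome 14, 54970684 to 54994626), fell from 1494 to 53.3 CPM at a slope of -1.03 ± 0.18. The other named genes that rose were the ADP-ribosyltransferase Art1 (slope 1.45), Scgb1c1 (1.43), the muscle fructose bisphosphatase Fbp2 (1.21), Hfe2 (1.184) and the nuclear receptor Rxrg (1.11). Those that fell were the X inactivation RNA Xist (-1.88), the glypican Gpc3 (-1.297), Nrk (-1.10), the LIM protein Csrp1 (-1.07) and the transcription factor Tcf21 (-1.03). Of 33188 genes tested, 393 rose and 234 fell, while 675 rose and 1109 fell in DESeq2, so the majority turns with the tool. Xist stood at 47.4 CPM at P1, 0.775 at P10 and 0.236 at P28, and at 0.309 at E18.5. The sex of the animals in each library was not examined here, so the slope of this X inactivation RNA is not read as an effect of age. Without P28, 7 of the 16 named genes no longer passed (Art1, Xist, H19, Igf2, Nrk, Csrp1 and Tcf21), and 147 genes passed in all. The number that passed was 1877 without P1, 400 without P4 and 358 without P14. Without P1 Myh7 no longer passed (slope -0.61). Without P14 the same holds for Xist (-1.79), Nrk (-0.87), Csrp1 (-0.93) and Tcf21 (-0.83), and without P3, P4 or P10 for Nrk (-1.10, -1.09 and -1.06) and Tcf21 (-1.02, -1.02 and -0.97).

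In CM, some genes of the working adult heart stood higher at older ages, though their list calls were lost with an estimated correlation. Of 21 genes on the adult sarcomere list, 4 rose (10 adjusted over the list alone) with a median fold of 3.35, among them Hrc, the titin cap Tcap (16.99-fold) and the mitochondrial creatine kinase Ckmt2 (21.7-fold). Hrc and Ckmt2 are not sarcomere proteins, while Myh6, Ttn and Myl2 did not pass (adjusted p = 0.283, 0.136 and 0.371, edgeR). Of 24 calcium and ion handling genes, 4 rose (12 adjusted over the list alone), among them Atp2a2, the calcium pump of the sarcoplasmic reticulum (19.5-fold), and the potassium channel gene Kcnd2 (26.2-fold). Of 36 oxidative phosphorylation genes, Cox7a1 and Cox8b, subunits of cytochrome oxidase, rose 16.4-fold and 14.8-fold in edgeR (21 rose adjusted over the list alone). All 36 had slopes above 0, but 0 of them passed in DESeq2. None of the 25 fatty acid oxidation genes passed over all genes (edgeR), while 12 passed adjusted over the list alone, 16 had an unadjusted p under 0.05 and 2 rose in DESeq2. Each of these lists was called upward by camera, with adjusted p of 1.3e-12, 9.4e-11, 1.4e-20 and 4.7e-12. With an estimated correlation between genes the calls were lost (adjusted p = 0.198 with an estimated correlation for sarcomere, calcium and oxidative phosphorylation, and 0.201 for fatty acid oxidation). At P7, where both isolations were made, the fractionated batch stood above the unfractionated one by a median log2 of 1.01 in the sarcomere list, 1.53 in the calcium list, 1.14 in oxidative phosphorylation and 0.53 in fatty acid oxidation. Within the unfractionated stages P1 to P7 the median slopes were -0.45, -0.50, -0.48 and -0.32, and within the fractionated stages P7 to P28 they were 0.55, 0.48, 0.41 and 0.37. The 10 cardiomyocyte markers stood 1.46 log2 units higher and the endothelial markers differed by -2.46 log2 units in the fractionated batch of CM at P7.

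Some imprinted and fetal growth genes fell in CM, though their list calls were lost with an estimated correlation. Of 14 imprinted growth genes, 8 fell (11 adjusted over the list alone) with a median fold of 0.0676, among them Dlk1 (slope -1.71 ± 0.15), the zinc finger gene Plagl1 (-0.99 ± 0.16), the growth factor receptor adaptor Grb10 (-0.71 ± 0.12) and Peg3 (-0.77 ± 0.14). Of 10 fetal Lin28 and Igf2bp genes, the mRNA-binding Igf2bp1, Igf2bp2 and Igf2bp3 fell (6 adjusted over the list alone). Of 14 genes on the fetal sarcomere list, Cnn1, Myl9 and Myh7 fell (2 up and 6 down adjusted over the list alone). Cnn1 is on the smooth muscle marker list as well. No cell cycle gene passed over all genes in edgeR, while 10 of 36 fell adjusted over the list alone, 19 fell at an unadjusted p under 0.05 and 15 fell in DESeq2, and 35 slopes were below 0. Camera called these lists downward with adjusted p of 1.3e-19 (imprinted), 4.6e-07 (Lin28 and Igf2bp), 0.00255 (fetal sarcomere) and 5.6e-22 (cell cycle). The adjusted p with an estimated correlation was 0.0865, 0.138, 0.198 and 0.198 in turn. The imprinted list had a median slope of -0.36 within P1 to P7 and of -1.34 within P7 to P28, and the cell cycle list 0.00 and -2.59. Within P7 to P28, a fit over few libraries, 6 of 14 imprinted, 23 of 36 cell cycle and 14 of 30 extracellular matrix genes were called. Fibroblast markers fell in CM in the same fit (median slope -1.77, 5 of 10 called). Whether RNA of other cells accounts for these falls was not tested. At P7 the fractionated batch of CM differed by a median log2 of -0.47 (imprinted), -0.69 (cell cycle) and -0.68 (extracellular matrix). These were 0.121, 0.253 and 0.393 times the fitted change from P1 to P28. Of 30 extracellular matrix genes Eln fell (5 adjusted over the list alone, camera adjusted p = 4.1e-10, and adjusted p = 0.198 with an estimated correlation). Of 10 fibroblast markers Tcf21 fell (4 adjusted over the list alone, camera adjusted p = 1.7e-07, and adjusted p = 0.198 with an estimated correlation). The glycolysis list was not called (adjusted p = 0.228, camera), though Aldoc (-1.84 ± 0.24) and Eno1 (-0.52 ± 0.11) fell and Hk2 rose (0.70 ± 0.14). Of the interferon and MHC list, H2-K1 rose (0.71 ± 0.15, camera adjusted p = 0.0106, and adjusted p = 0.266 with an estimated correlation).

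The lists of the RNA machinery held few called genes in CM. No member of the SR and hnRNP list (46 genes, 37 with slopes below 0, 12 down at an unadjusted p under 0.05 and 2 falling in DESeq2), the spliceosome (51 genes, 2 up and 5 down unadjusted) or the muscle splicing regulators (16 genes, 1 up and 1 down unadjusted, 1 falling in DESeq2) passed in edgeR over all genes. Camera called only the first of these 3 (downward, median fold 0.718, adjusted p = 0.0015, and adjusted p = 0.66 with an estimated correlation), with adjusted p of 0.64 for the spliceosome and 0.806 for the regulators. Cap binding (adjusted p = 0.917), stress granule (0.417), dissociation response (0.917), endothelial maturation (0.806) and the genes with known splicing events (0.299, with 11 rising and 4 falling of 59 adjusted over the list alone) were not called by camera in CM. Markers of other cells moved in CM too. Of 6 T cell markers 4 rose, of 7 pericyte markers 2, of 5 B cell markers 2 and of 8 macrophage markers 1, while 2 of 5 granulocyte markers and 1 of 5 smooth muscle markers fell. Erythroid markers were called downward by camera (adjusted p = 1.3e-05, and adjusted p = 0.198 with an estimated correlation) and cardiomyocyte markers upward (0.00168, and adjusted p = 0.405 with an estimated correlation). Endothelial (0.0745), endocardial (0.483), epicardial (0.847) and Schwann cell (0.299) markers were not called. The camera direction was up while the median slope was below 0 for cap binding (-0.06) and endothelial maturation (-0.08), and for the muscle splicing regulators the mean slope was -0.0042 and the median 0.03.

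**Figure D1:**
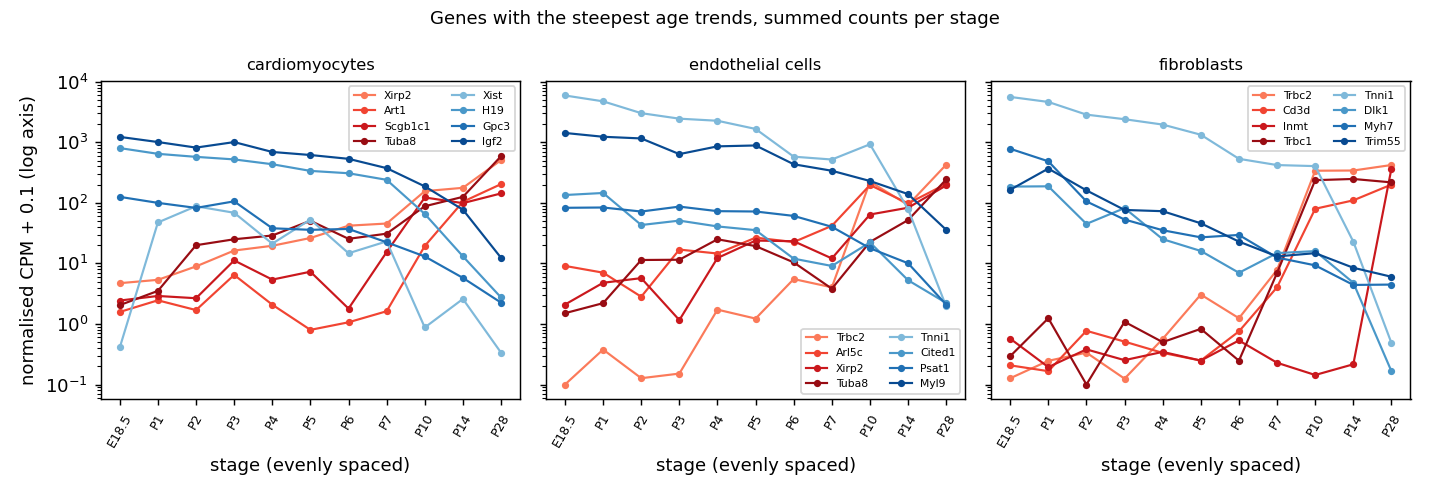
Normalised CPM (log axis, 0.1 added) of the 4 steepest rising and 4 steepest falling named genes against stage, with 1 panel for each of CM, EC and FB and 1 point per library. Xirp2 in CM goes from 5.26 CPM at P1 to 507 at P28, and Inmt in FB is high at P28 alone (368 CPM).

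In EC, some T cell receptor, dissociation response and MHC genes rose, and some fetal sarcomere and imprinted genes fell, though for dissociation response and MHC the list calls were lost with an estimated correlation (adjusted p = 0.0951 and 0.216 with an estimated correlation). Trbc2, the constant region of the T cell receptor beta chain, had the steepest slope (2.70 ± 0.45, from 0.278 to 428 CPM, adjusted p = 0.00557, edgeR). Hes1, a repressor downstream of Notch, rose from 21.3 to 329 CPM (slope 1.05 ± 0.21), and Cytl1, a secreted protein of the endocardial marker list (chromosome 5, 37735519 to 37739820), from 71.9 to 1012 CPM (0.95 ± 0.21). Tnni1, the slow troponin I of the fetal heart (chromosome 1, 135783033 to 135810989), fell from 4747 to 1.84 CPM (-1.60 ± 0.36), and Cited1, a transcriptional coregulator, from 146 to 2.12 CPM (-1.17 ± 0.16). The other named genes were Arl5c (1.27), Xirp2 (1.24), Tuba8 (1.17), Lrtm1 (1.11) and Hrc (1.07), which rose, and the serine synthesis enzyme Psat1 (-1.10), Myl9 (-1.07), Myh7 (-1.01), Gpc3 (-0.96), Bex1 (-0.87) and Csrp1 (-0.87), which fell. Of 30534 genes tested, 440 rose and 93 fell (838 and 789 in DESeq2). In cells that the authors' finer annotation also names EC, the slopes of Xirp2, Tuba8, Lrtm1 and Hrc were -0.02, -1.71, -0.46 and -0.90, so their direction turned. The number that passed was 1265 without P1, 265 without P2, 311 without P3, 263 without P4 and 75 without P28. Without P28, Tuba8, Hrc, Hes1, Cytl1, Psat1, Gpc3, Bex1 and Csrp1 no longer passed. Psat1, Csrp1, Gpc3, Cytl1 and Tnni1 each lost their call without at least 1 of P2, P3, P4, P6 and P14 as well.

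Of 20 dissociation response genes, immediate early and heat shock genes known to rise while tissue is digested, 7 rose in EC (16 adjusted over the list alone) with a median fold of 6.08, among them Egr1 (19.5-fold) and Junb (15.2-fold). Of 19 interferon and MHC genes, 6 rose (7 adjusted over the list alone), among them the class II chain H2-Aa (97.4-fold) and Cd74 (32.1-fold). Of 26 endothelial maturation genes, the transcription factor Tcf15 (19.2-fold), the water channel Aqp1 (5.27-fold) and the VEGF receptor Flt1 (5.79-fold) rose (6 adjusted over the list alone). Of 14 fetal sarcomere genes 4 fell (7 adjusted over the list alone), of 14 imprinted genes 3 (8), and of 10 Lin28 and Igf2bp genes 4 (5), Lin28b at -1.41 ± 0.26. Camera called these 6 lists with adjusted p of 2.5e-18, 2.3e-08, 9.8e-05, 5.0e-08, 9.2e-09 and 9.9e-07. The adjusted p with an estimated correlation was 0.0951, 0.216, 0.223, 0.0152, 0.0152 and 0.0514 in turn. At P7 the dissociation list stood 1.03 log2 units higher in the fractionated batch, and its median slope was -0.10 within P1 to P7 and 0.31 within P7 to P28. Markers of other cells rose beside these genes: 5 of 6 T cell markers (camera adjusted p = 1.2e-14, and 0.0182 with an estimated correlation) and 3 of 8 macrophage markers (8.5e-05, and adjusted p = 0.216 with an estimated correlation). The T cell markers reached 38.1 CPM in EC at P28, with a median over markers of 2.96% of the level in annotated T cells. The 10 cardiomyocyte markers stood in EC at a median of 58.7% of the CM level at P1 and 46.7% at P28. Hrc, Tcap, Ckmt2 and Cmya5 of the adult sarcomere list rose in EC as well (camera adjusted p = 2.0e-05, and adjusted p = 0.447 with an estimated correlation).

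In FB, some matrix, dissociation response and MHC genes rose, with list calls lost at an estimated correlation (adjusted p = 0.167, 0.138 and 0.201 with an estimated correlation), and some genes of the fetal sarcomere fell. Pi16, a peptidase inhibitor known from fibroblasts around vessels (chromosome 17, 29318796 to 29328903), rose 502-fold in the fit (slope 1.87 ± 0.17, adjusted p = 1.9e-05, edgeR). Its measured level was 2.03 CPM at P1 and 574 at P28. H2-Aa rose from 0.798 to 317.5 CPM (1.81 ± 0.22), and Trbc2 from 0.146 to 422 CPM (3.18 ± 0.53). Dlk1, an imprinted regulator of differentiation (chromosome 12, 109452485 to 109463336), fell from 188 to 0.0658 CPM (-1.57 ± 0.27), Myh7 from 485.5 to 4.37 CPM (-1.45 ± 0.12) and the muscle ubiquitin ligase Trim55 from 368 to 5.92 CPM (-1.33 ± 0.12). Inmt, a methyltransferase, was high at P28 alone (0.0941 CPM at P1, 368 at P28), and its slope went from 2.46 ± 0.43 to -0.12 without P28. The other named genes were Cd3d (2.74), Trbc1 (2.19), Ifi205 (2.04) and Wisp2 (1.83), which rose, and Tnni1 (-2.08), Clca1 (-1.27), the decarboxylase Ddc (-1.185), Csrp1 (-1.15) and the uridine phosphorylase Upp1 (-1.08), which fell. Of 31049 genes tested, 1282 rose and 407 fell (1517 and 1267 in DESeq2). The number that passed was 3113 without P1, 798 without P2, 1050 without P3, 1076 without P4 and 493 without P28. Trbc1 (2.29), Wisp2 (0.36), Clca1 (-0.86), Csrp1 (-0.97) and Upp1 (-0.80) no longer passed without P28, nor did Clca1 without P2 (-1.37), P3 (-1.23) or P14 (-1.05), or Trbc1 without P3 (2.15). With the level of cardiomyocyte markers as a covariate, 2 genes passed (3884 at an unadjusted p under 0.05).

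Of 30 extracellular matrix genes, 10 rose in FB (21 adjusted over the list alone) with a median fold of 2.91, among them the lysyl oxidase Loxl1 (10.3-fold), Smoc2 (22.97-fold) and the collagen-binding Dcn (14.3-fold). Of 20 dissociation response genes, 15 rose (19 adjusted over the list alone) with a median fold of 13.1, among them Nr4a1 (22.6-fold) and Atf3 (33.0-fold), and of 19 interferon and MHC genes 7 rose (11). Of 14 fetal sarcomere genes 7 fell (9 adjusted over the list alone), among them Myl4 (-0.97 ± 0.14) and Acta2 (-0.76 ± 0.15), and of 20 glycolysis genes 6 fell (13), among them Ldha (-0.45 ± 0.10). Camera called these lists with adjusted p of 6.0e-15, 1.4e-22, 9.7e-10, 1.3e-16 and 9.4e-13. The adjusted p with an estimated correlation was 0.167, 0.138, 0.201, 0.0075 and 0.17 in turn. Of 16 muscle splicing regulators, Rbpms2 (-0.94 ± 0.16), Rbm24 (-0.55 ± 0.12), Rbm20 (-0.76 ± 0.17) and Srpk3 (-0.74 ± 0.19) fell (camera adjusted p = 0.0223, and adjusted p = 0.278 with an estimated correlation). Among SR and hnRNP genes Tra2a and Hnrnpul2 rose (camera adjusted p = 0.000443, and adjusted p = 0.502 with an estimated correlation). Cardiomyocyte markers fell beside the muscle genes: 4 of 10 fell, and the median over markers of their level in FB went from 55.0% of that in CM at P1 to 10.6% at P28. T cell (5 of 6) and macrophage markers (5 of 8) rose beside the MHC genes, and 3 of 10 fibroblast markers rose beside the matrix genes. The dissociation list stood 1.71 log2 units higher in the fractionated P7 batch, with a median slope of -0.06 within P1 to P7 and 0.52 within P7 to P28.

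**Figure D2:**
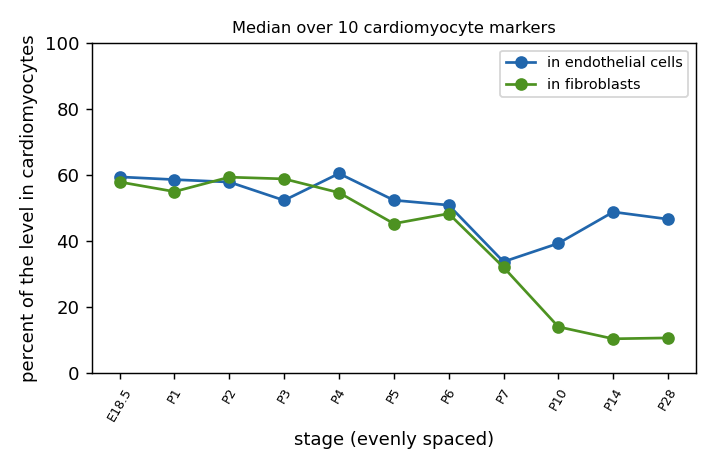
Median over 10 cardiomyocyte markers of the level in EC and in FB as percent of that in CM, against stage, with 1 point per library. It goes from 58.7% to 46.7% in EC and from 55.0% to 10.6% in FB between P1 and P28.

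Differences between types were tested as the interaction of type and age. Between CM and FB 745 genes differed, 327 steeper upward in FB and 418 in CM. The stage block does not remove a change of isolation that acts differently on the types. At P7 the fractionated batch differed in the dissociation list by a median log2 of 0.15 in CM and 1.71 in FB. No interaction was fitted within 1 isolation, so isolation and age cannot be told apart in these differences. Lrtm1 rose in CM (slope 1.11) and had a slope of 0.14 in FB, a difference of -0.97 ± 0.17 (adjusted p = 0.0173, edgeR). Of the lists, 19 of 21 adult sarcomere genes, 35 of 36 oxidative phosphorylation genes and 14 of 25 fatty acid oxidation genes were steeper in CM, with median differences of -0.69, -0.46 and -0.50, and 9 of 10 cardiomyocyte markers were too. In FB the cardiomyocyte markers had a median slope of -0.37. Whether a loss of cardiomyocyte RNA from wells of FB accounts for these list differences was not tested. Of the matrix list 15 of 30 and of the dissociation list 13 of 20 were steeper upward in FB (median differences 0.84 and 0.92). Between EC and FB 18 genes differed, Pi16 by 1.05 ± 0.13 (0.87 in EC, 1.87 in FB, adjusted p = 0.0221). Between CM and EC 0 of 35487 genes passed in edgeR, with 3364 at an unadjusted p under 0.05, and 0 passed with DESeq2 size factors (DESeq2's own test was not run on interactions). The CM and FB count was 2178 without P1, 314 without P3, 367 without P4, 144 without P10, and 0 without P2, P14 or P28 (5070, 5222 and 3614 at an unadjusted p under 0.05). The EC and FB count was 736 without P1, 56 without P6, 54 without P7, 8 without P5, 5 without P10, 2 without P3, and 0 without P2, P4, P14 or P28 (3655, 3601, 4182 and 2776 unadjusted). Without P1 147 genes passed between CM and EC.

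The next comparison asks how the mRNAs of the 3 proteins used for CLIP move with age. Ptbp1, a splicing repressor (chromosome 10, 79854432 to 79864435), stood in CM at 71.1 ± 24 CPM at P1 (SD, n = 4 units), 147 ± 46.8 at P4 (n = 5), 23.8 ± 3.05 at P10 (n = 2) and 4.46 ± 2.41 at P28 (n = 4). Its slope in CM was -0.83 ± 0.22, a fitted fold of 0.0621, with an adjusted p of 0.0505 in edgeR that misses the threshold. In EC the slope was -0.52 ± 0.16 (adjusted p = 0.108) and in FB -0.44 ± 0.15 (0.105). Ncbp2, a subunit of the nuclear cap-binding complex (chromosome 16, 31948546 to 31958472), had slopes of 0.08 ± 0.11 in CM (adjusted p = 0.868), 0.05 ± 0.10 in EC (0.929) and 0.27 ± 0.13 in FB (0.28). G3bp1, a stress granule protein (chromosome 11, 55469657 to 55500888), had slopes of -0.0079 ± 0.10 in CM (0.989), -0.09 ± 0.10 in EC (0.794) and -0.02 ± 0.11 in FB (0.968). None of these 9 trends passed in edgeR, 1 had an unadjusted p under 0.001 (Ptbp1 in CM, 0.000964), and Ptbp1 in CM passed in DESeq2 (adjusted p = 0.000459). Over the alternatives its adjusted p in CM also fell under the threshold without P1 (0.00196), P6 (0.0427) or P7 (0.0334). The same held with no filter (0.0444), the unlogged day (0.000404), no ribosomal protein genes (0.0495) and batch P7 alone (0.0383). With units as samples and the stage as a random block it was 0.00526 (limma). In EC it passed without P1 (0.0194) and with the random block (0.0284), and in FB without P1 (0.0104) and with the unlogged day (0.0432). The random block setting takes 40 units as samples while age varies only between 10 stages, so its p can be too small. Within P1 to P7 the slope of Ptbp1 in CM was 0.09.

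**Figure D3:**
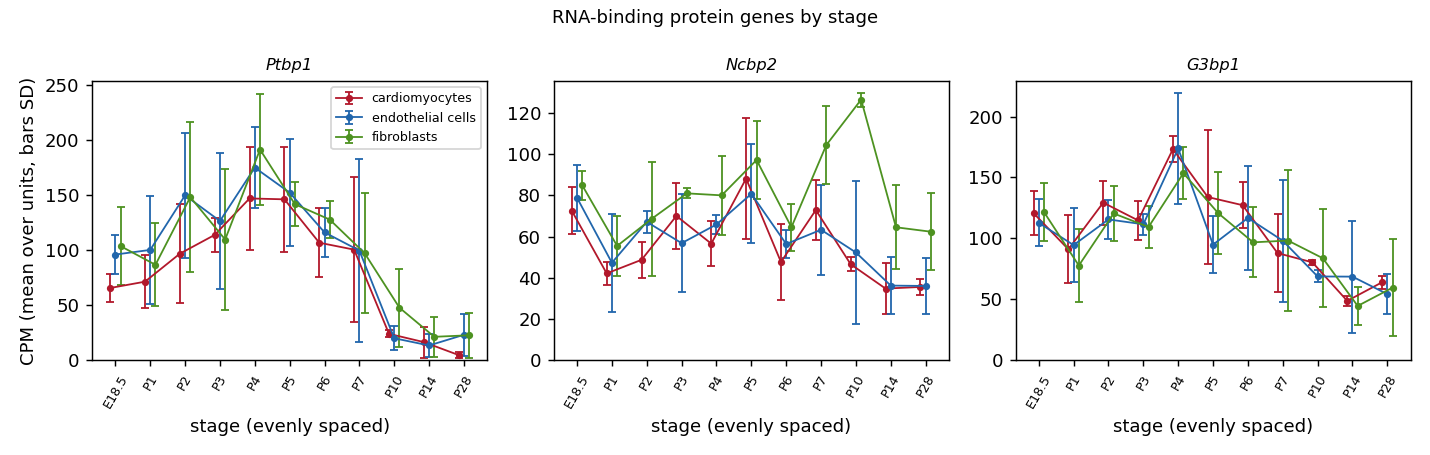
Mean CPM over units of Ptbp1, Ncbp2 and G3bp1 in CM, EC and FB against stage, with bars of 1 SD over the units of a stage. Ptbp1 in CM is 147 at P4 and 4.46 at P28.

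Exon inclusion asks which exons switch with age. Ldb3 (chromosome 14, 34526699 to 34590314), a Z-disc protein, had 1 event whose PSI fell in CM from 0.719 at P1 to 0.0867 at P28 (adjusted p = 0.0292, limma). An event of Ttn, the giant sarcomere spring, fell from 0.663 to 0.0263 (0.0218), and Myom1, an M-band protein, from 0.126 to 0.0207 (0.0218). Of the 59 genes with known splicing events 27 were tested, and 4 had a called event. The largest changes included Atf2 (0.890 to 0.041, chromosome 2, 73816509 to 73892677), Trip4 (0.977 to 0.317), Preb (0.710 to 0.0333) and Dnal4 (0.985 to 0.135) over P1 to P28. Trub2 went from 0.922 at P1 to 0.0329 at P10, and Stard4 (0.946 to 0.214) and Gnpda1 (0.966 to 0.0979) changed from P1 to P14, the last stages with values. In EC, Ldb3 (0.718 to 0.0275), Ttn (0.681 to 0.0139), Atf2 (0.831 to 0.0393) and Cnot7 (0.867 to 0.0493) changed alike. In FB, Ldb3 (0.717 to 0.024), Ttn (0.687 to 0.000487) and Slc9a3r2 (0.795 to 0.0267) did too. Whether cardiomyocyte RNA in wells of EC and FB accounts for the Ldb3 and Ttn events there was not tested. Gprasp1 in EC fell from 0.924 to 0.00579 and stood at 0.0208 at E18.5, and Hand2os1 rose from 0.0653 to 0.918 and stood at 0.854 at E18.5. In CM 80 events were called (5 up, 75 down), in EC 44 (4 up, 40 down) and in FB 51 (5 up, 46 down), with 37 shared by CM and EC, 34 by CM and FB, and 39 by EC and FB, none in opposite directions. Across events, which are not independent replicates, the changes correlated at r = 0.980 (CM and EC), 0.969 (CM and FB) and 0.994 (EC and FB), and permuted ages gave 0.886 to 0.9902, 0.810 to 0.985 and 0.974 to 0.995. In cells away from the value shared by most cells of a stage, Ldb3 kept its call in CM (adjusted p = 0.0162) and lost it in EC (0.0895) and FB (0.219), while Ttn kept it in all 3 types (0.00666, 0.0026 and 0.00184). Without P6 and P10, 10 of 10 named events in CM, 8 of 8 in EC and 7 of 8 in FB lost their calls, and with the unlogged day 5 of 11, 9 of 9 and 9 of 9 did. The number of calls in CM was 1 without P1, 52, 34, 45, 30 and 49 without P2 to P6, 180 without P7, 36 without P10, 18 without P14 and 53 without P28. In EC it was 0 without P1 (200 at an unadjusted p under 0.05 in limma, no other tool was run), 85 without P7 and 26 without P10. In FB it was 0 without P1 (246 unadjusted), 33 without P3, 32 without P5, 31 without P10 and 29 without P14.

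**Figure D4:**
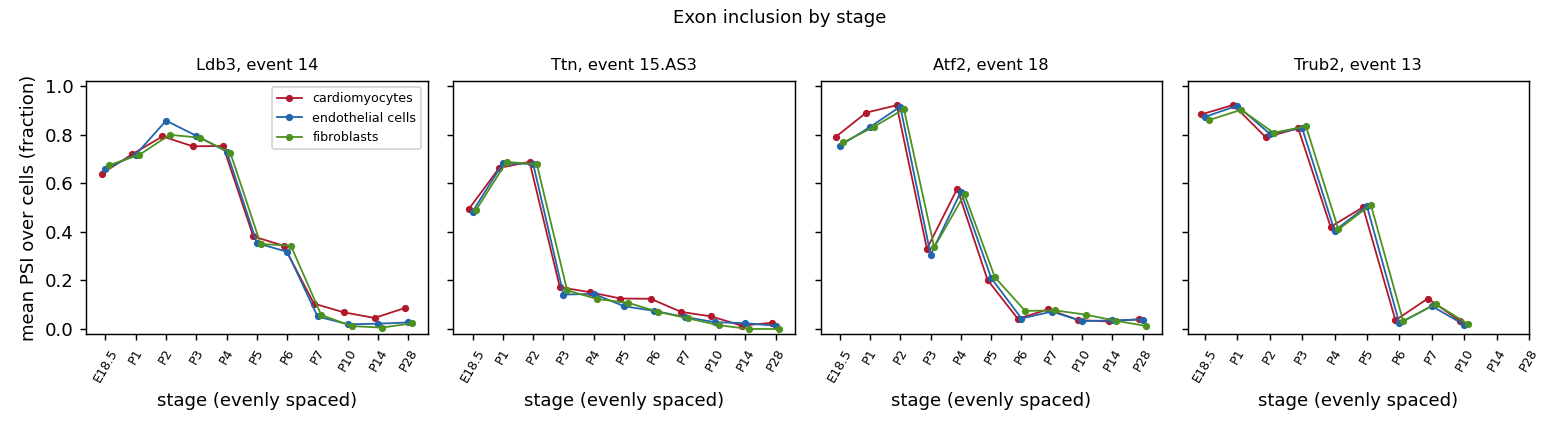
Mean PSI (fraction) of events in Ldb3, Ttn, Atf2 and Trub2 against stage in CM, EC and FB, with 1 point per library. Ldb3 in CM goes from 0.719 to 0.0867, and Trub2 has no value at P14 and P28.

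The CLIP lists ask which RNAs G3BP1, NCBP2 and PTBP1 bind in neonatal CM, EC and FB. The genes with the highest mean CPM on the lists of all 3 types were Tnnt2, Ttn, Myh6, Atp2a2, Atp5o and the nuclear RNA Malat1 for each protein, Cd36 for G3BP1 and NCBP2, and Eif4g2 (G3BP1), Fstl1 (NCBP2), Actc1 and Cav1 (PTBP1). In all, 381 genes were on the 3 lists of G3BP1, 336 on those of NCBP2 and 301 on those of PTBP1. In CM, 27 of 59 genes with known splicing events were on the G3BP1 list, 35 on the NCBP2 list and 28 on the PTBP1 list. Ryr2, Camk2d, Tpm1 and Mbnl2 were among them. Of 14 imprinted genes, Grb10, H19, Igf2, Igf2r, Meg3 and Mest were on the G3BP1 list in CM, while the NCBP2 list held 6 and the PTBP1 list 8. Of 33188 genes tested in CM, 1056, 2345 and 1455 were on the lists of G3BP1, NCBP2 and PTBP1. In FB, falling genes were over-represented: 41 for G3BP1 (odds ratio 2.47, 95% interval 1.78 to 3.42, adjusted p = 7.6e-06), 30 for NCBP2 (2.90, 1.99 to 4.24, 7.6e-06) and 54 for PTBP1 (2.44, 1.83 to 3.27, 1.1e-06), by Fisher's exact test. Random lists of like expression held a median of 30, 18 and 40 falling genes, and the real counts stood at percentiles 98.5, 99.7 and 99.2. With the calls of DESeq2 the odds ratios were 1.32, 1.49 and 1.23 (adjusted p = 0.0605, 0.0309 and 0.114). Cardiomyocyte markers fell in FB as well, from 55.0% to 10.6% of the CM level, and Tnnt2, Ttn and Myh6 are on the FB lists. Whether cardiomyocyte RNA accounts for these odds ratios was not tested. Rising genes in FB had odds ratios of 1.47, 1.54 and 1.70 but stood below the lists of like expression, at 0.714, 0.776 and 0.819 times their median. In CM, falling genes had odds ratios of 1.797 for NCBP2 (adjusted p = 0.0222) and 2.05 for PTBP1 (0.021), at 0.848 and 1 times that median. No table with called exon events passed after correction (lowest adjusted p = 0.0577, NCBP2 in CM, odds ratio 1.83), 2 had an unadjusted p under 0.05, and no other test was run. All 18 overlaps between lists passed (odds ratios 21.1 to 89.1) and stood above all lists of like expression.

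Shares of cell types ask how the make-up of the non-cardiomyocytes changes. GR fell from 3.05% at P1 (64 of 2101 cells, exact interval 2.35 to 3.87) to 0.7% at P28 (7 of 1000, 0.282 to 1.44), and MyoFB fell from 9.04% to 1.5%. T rose from 4.05% to 22.9%, MP from 5.52% to 15.3%, and the share of EC fell from 30.9% to 21.7%. These are parts of 1 total, so a rise of T and MP lowers the other shares, and whether EC fell relative to the rest was not tested. Cells annotated T had a median of 7.01 CPM over the 6 T cell markers at P1 and 1769 at P28, so what the T share counts at early stages is in doubt. Over 10 stages and 11 types in the family, GR had rho = -0.952 (permutation p = 0.00015, adjusted 0.00165) and r = -0.904 (0.00022, adjusted 0.00132), and -0.896 without P1 and P28. MyoFB had rho = -0.891 (permutation p = 0.00128, adjusted 0.00704) and r = -0.906 (0.00024, adjusted 0.00132), and -0.863 without P1 and P28. For T, r was 0.832 (permutation p = 0.00234, adjusted 0.00858) and rho 0.733 (0.021, adjusted 0.077), with r = 0.698 without P1 and P28 over 8 stages (permutation p = 0.0555). For MP, r was 0.770 (permutation p = 0.00716, adjusted 0.0189) and rho 0.697 (0.0313, adjusted 0.086), with r = 0.655 without P1 and P28 (permutation p = 0.0751). Without P1 and P28 the calls of T and MP were thus lost while r stayed above 0.6. Within the unfractionated stages P1 to P7, r of both was lower still, and rho of T turned negative. For EC r was -0.776 (0.00858, adjusted 0.0189) and rho -0.661 (0.0447, adjusted 0.0984), with -0.379 without P1 and P28 (permutation p = 0.348), so this relation rests on those stages. FB (r = -0.602, adjusted p = 0.109, permutation), B, ER, PC, SMC and rMP were not called. Within the unfractionated stages P1 to P7, GR alone passed (rho = -0.964, exact permutation p = 0.00278, adjusted 0.0306), while P7 to P28 holds too few stages for a correlation. At P7 the unfractionated and fractionated batches held 31.6% and 19.3% EC, 2.88% and 11.5% T, and 24.7% and 33.0% FB.

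**Figure D5:**
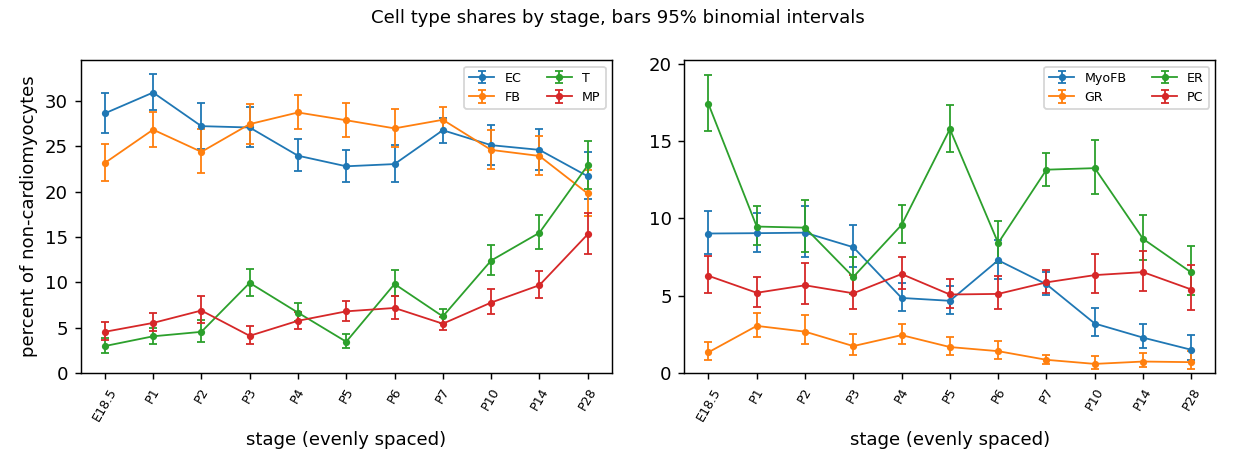
Share of non-cardiomyocytes (percent) annotated EC, FB, T, MP, MyoFB, GR, ER and PC against stage, with exact 95% intervals. T goes from 4.05% at P1 to 22.9% at P28, and GR from 3.05% to 0.7%.

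E18.5 and P1 stand on both sides of birth, as single libraries without a test. Interferon and MHC genes were higher at P1 in all 3 types, with median log2 ratios of 1.303 in CM (16 of 19 genes higher), 0.93 in EC and 1.42 in FB. Each stood at percentile 100 of random lists. Those lists were not matched on expression and ignore correlation between genes of a list, so the percentile is not a test. Oxidative phosphorylation genes were higher too (0.22, 0.35 and 0.40, with 35, 34 and 35 of 36 genes higher). Glycolysis genes were lower (-0.31 in CM and -0.35 in FB), and erythroid markers were lower (-0.49, -0.68 and -0.93). On library totals without TMM factors, Igf2 in CM stood at 1174.2 CPM at E18.5 (exact Poisson interval 1171.1 to 1177.3) and 912.06 at P1 (909.47 to 914.65), and Myh7 at 1895.7 and 1349. Endothelial markers stood 1.27 log2 units higher at P1 in CM and 0.75 in FB.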

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

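Tests chosen only after the result was seen are those of exon inclusion against depth and against the shared value, those of isolation for the lists that rose or fell in CM, and the fits within P7 batches, with marker levels and with finer names, while the tests of dissociation genes, of slopes of cardiomyocyte genes and of permuted ages were planned. Each stage is 1 library, so no group of samples was large enough to ask whether a sample stands apart from its group. The results here were singled out because the age trend differed between 2 cell types by the interaction test of edgeR.

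Between CM and FB 745 genes differed, and between EC and FB 18. Steeper upward in FB than in CM were Medag, a fat cell differentiation gene (difference 1.59 ± 0.37, slopes -0.57 in CM and 0.90 in FB), the Wnt antagonist Sfrp1 (1.58 ± 0.32, -0.97 and 0.48), the calcium-binding S100a4 (1.48 ± 0.29, -0.52 and 0.92), the stress regulator Nupr1 (1.48 ± 0.36, -0.06 and 1.24) and the small GTPase Gem (1.43 ± 0.35, -0.52 and 0.82). Steeper upward, or less steep downward, in CM were Aldh1b1, a mitochondrial aldehyde dehydrogenase (-1.10 ± 0.27, -0.73 in CM and -1.83 in FB), Lrtm1 (-0.97 ± 0.17, 1.11 and 0.14), the nicotinamide riboside kinase Nmrk2 (-0.95 ± 0.15, -0.21 and -1.14), the glycogen phosphatase subunit Ppp1r3a (-0.91 ± 0.15, 0.19 and -0.72) and the lipid droplet gene Cidea (-0.90 ± 0.15, 0.52 and -0.38). Steeper upward in FB than in EC were Oaf (1.25 ± 0.18, slopes -0.42 in EC and 0.77 in FB), Pi16 (1.05 ± 0.13, 0.87 and 1.87), the chemokine scavenger Ackr3 (0.98 ± 0.13, 0.06 and 1.07), the microfibril protein Mfap5 (0.74 ± 0.11, 0.31 and 1.03) and the actin-severing Gsn (0.60 ± 0.10, 0.41 and 0.92). Steeper upward in EC were the muscle genes Smpx (-0.57 ± 0.09, 0.02 in EC and -0.54 in FB) and Pln (-0.57 ± 0.09, 0.13 and -0.46), and the mitochondrial genes Cox5a (-0.54 ± 0.09, 0.51 in EC), Mgst3 (-0.47 ± 0.08, 0.40 and -0.07) and Hadhb (-0.42 ± 0.07, 0.25 and -0.19). Adjusted p for these genes lay between 0.0173 and 0.0486. The cardiomyocyte markers fell in FB (median slope -0.37). Whether a loss of cardiomyocyte RNA from wells of FB accounts for the muscle and mitochondrial genes here was not tested. No interaction was fitted within the fractionated or the unfractionated stages alone, so isolation stays open for all of these differences. Without P2, P14 or P28, 0 genes passed in either comparison, nor without P4 between EC and FB.

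The interaction test was run in 21 orders of the ages, the real one included. Between CM and FB it called 745 genes in the real order only (1 order as large, highest other 0). Between EC and FB it called 18 in the real order only (1, highest other 0). This argues against chance for both, but 21 orders are too few to exclude it. Without P2, P14 or P28, 0 genes passed in either comparison. Between CM and EC the real order gave 0, as did every other (21 as large, highest other 0), so there is no count to set against chance. For the age trend within a type chance was not excluded: 3 of 40 orders gave as many genes as the real 627 in CM (highest other 1219), 3 as the real 533 in EC (highest other 1091) and 3 as the real 1689 in FB (highest other 2917). The same 2 permuted orders exceeded the real one in each type, 1 with a correlation of -0.684 with the real log2 day and 1 with 0.577. For exon inclusion permuted orders argue against chance. In CM 2 of 100 orders, the real one included, reached the real 80 events (highest other 109). The real order alone reached 44 in EC (highest other 2) and 51 in FB (highest other 6). An effect of single libraries is not excluded, since without P1 the calls came to 1 in CM and 0 in EC. The 3 types share libraries, so they are not independent support.

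In CM, 4 of 21 adult sarcomere, 4 of 24 calcium handling and 2 of 36 oxidative phosphorylation genes rose with age in edgeR (3, 3 and 0 in DESeq2). The list calls were lost with an estimated correlation (camera adjusted p = 0.198 each). At P7 the fractionated batch (as read from the names of units) stood above the unfractionated one in these lists. The median difference was 0.576 (sarcomere), 0.815 (calcium) and 0.616 (oxidative phosphorylation) times the fitted change from P1 to P28, so the change of isolation may account for much of these rises. Within the fractionated stages, P7 to P28, 20 of 21, 22 of 24 and 36 of 36 slopes were above 0, but within P1 to P7, before the isolation changes, 1 of 21, 2 of 24 and 0 of 36 were, so isolation stays open. It is argued against for the falling imprinted genes, with a ratio of 0.121 and with 2 and 0 of 14 slopes above 0 within P1 to P7 and P7 to P28. For fatty acid oxidation genes in CM (0.329) and dissociation response genes in EC (0.396) and FB (0.461) isolation and age cannot be told apart, because the batch difference is neither small nor most of the change, with 22 of 25, 14 of 20 and 19 of 20 slopes above 0 within P7 to P28 and 3, 3 and 9 within P1 to P7. Age, which the design names, stays open for all of these lists as an untested explanation, as do cell quality and the digestion, which differ between neonatal and adult protocols.

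Part of the genes that changed in EC and FB are cardiomyocyte genes: 35 of the EC calls and 140 of the FB calls were at least 2-fold higher in CM. Across these genes, which are not independent replicates, slopes correlated with those in CM at r = 0.771 in EC and 0.929 in FB, as cardiomyocyte RNA in wells of the other types may give, against 0.603 and 0.564 for called genes at least 2-fold lower in CM, and 602 EC carry the finer name EC_cm, while in cells named EC alone the slopes of Xirp2, Tuba8, Lrtm1 and Hrc turned to -0.0212, -1.71, -0.46 and -0.90. With the finer name, 8 of 16 named genes in EC kept their call, 4 lost it and 4 turned, while in FB 15 of 16 kept it. Against cardiomyocyte RNA as the whole cause, 529 genes in EC (460 rising, 69 falling) and 1781 in FB (1622 rising, 159 falling) passed among genes at least as high there as in CM, of which 380 and 1327 were called over all genes as well. A gene that rose passes this filter more easily, and in FB, where the markers fell and 407 genes fell over all genes, cardiomyocyte RNA stays open for the falling genes. With the marker level as covariate 288 genes passed in EC and 2 in FB, where that level itself drops with age, so the covariate and age cannot be told apart there, and age remains open as an untested explanation.

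Most called exon events fell with age, 75 of 80 in CM, 40 of 44 in EC and 46 of 51 in FB. In cells away from the value that most cells of a stage share, most testable called events kept their direction with a change of at least 0.10. The shares were 96.25% (CM), 90.9% (EC) and 90% (FB), which argues against that value alone as the cause. Fewer events kept their call, 62 of 80 in CM and 24 of 44 in EC. Values in these cells come from the same model, so a shared estimate is not excluded. Depth stays open: given log2 day, mean PSI in CM and the median number of genes per cell had a partial correlation of 0.514 over 10 stages, and P6, the stage with the lowest assigned share of reads, had a mean PSI of 0.445 against 0.528 at P7. The near-identical changes in CM, EC and FB (r of 0.980, 0.969 and 0.994) may come in part from an estimate shared between the cells of a stage. Whether cardiomyocyte RNA in wells of EC and FB adds to them was not tested. Permuted orders of the ages gave r between 0.886 and 0.9902, 0.810 and 0.985, and 0.974 and 0.995, ranges that hold the real values, while the estimate itself could not be examined because the tool is not given, and age stays open as untested.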

How the results depend on the processing

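Alternatives chosen after the data were seen are the P7 batches, the stage subsets, the finer cell names, the cardiomyocyte markers as covariate, the units as samples with the stage as a random block, the removal of P6 and P10, and exon inclusion in cells with reads or away from the shared value. For each value below that moved, lost its call or turned, the cause was not tested, except that subsets of stages hold fewer libraries. DESeq2 size factors moved no count of the age trend by over 1.5 times, nor did the absence of a filter or a minimum count of 50. The median slope over all genes moved by over 0.1 with mean CPM per cell (-0.10 in CM), within P1 to P7 (0.27 in CM, 0.12 in EC, 0.20 in FB), within P7 to P28 (-0.11 in FB) and with the cardiomyocyte covariate (0.24 in FB). On simulated data the trend test recovered 31.3% of genes at a slope of 0.5 and none at 0.25, so smaller slopes can be missed, and PSI has no read depth to give. The PSI settings with at least 5 or 20 cells moved nothing, since every cell has a value, and the comparison of Ncbp2 overexpression was not run.

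In CM the 627 calls of the age trend became 1784 with DESeq2 (377 rising and 231 falling genes shared), 2551 with the unlogged day, 394 with mean CPM per cell, 107 within P1 to P7, 399 within P7 to P28 and 2577 with units as samples and the stage as a random block. In this last setting 40 units count as samples while age varies only between 10 stages, so its counts can be too high. In EC the 533 calls became 1627 with DESeq2, 953 on stage rank, 2185 with the unlogged day, 257 with equal cells, 800 with the finer name, 288 with the cardiomyocyte covariate, 338 with batch P7 alone, 62 within P1 to P7, 0 within P7 to P28 (edgeR, 2588 unadjusted) and 1411 with the random block. In FB the 1689 calls became 2784, 2598 on stage rank, 3589 with the unlogged day, 998 with equal cells, 499 with the depth covariate, 2 with the cardiomyocyte covariate, 186 within P1 to P7, 0 within P7 to P28 (2241 unadjusted) and 2740 with the random block. With each stage left out in turn the count ran from 147 (without P28) to 1877 (without P1) in CM, from 75 to 1265 in EC and from 493 to 3113 in FB. The share that rose was 62.7% in CM, 82.6% in EC and 75.9% in FB, against 37.8%, 51.5% and 54.5% in DESeq2. Lists called by camera, 19 in CM, 21 in EC and 24 in FB, became 0, 3 and 1 with an estimated correlation.

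Ptbp1 in CM passed the threshold at slopes of -0.81 (DESeq2), -0.83 (no filter), -0.16 per day (unlogged day), -0.83 (without ribosomal protein genes), -0.92 (batch P7 alone) and -0.56 (random block), and turned to 0.0874 within P1 to P7, with -1.15 (without P1) to -0.53 (without P28) leaving out stages. In EC it passed at -0.43 with the random block, with -0.71 (without P1) to -0.43 (without P14). In FB it passed at -0.0724 per day with the unlogged day and stood at 0.16 with the covariate, with -0.63 (without P1) to -0.37 (without P14). Ncbp2, never called, turned in CM to -0.00047 (stage rank), -0.11 (mean CPM) and -0.12 (P7 to P28), in EC to -0.0239 (stage rank), -0.0163 (mean CPM), -0.0213 (P1 to P7) and -0.0364 (P7 to P28), and in FB to -0.10 (covariate) and -0.27 (P7 to P28). G3bp1, never called, turned in CM to 0.010016 (DESeq2 size factors), 0.010015 (DESeq2), 0.0047 per day (unlogged day) and 0.30 (P7 to P28), with -0.0853 (without P28) to 0.0362 (without P14). In EC it turned to 0.21 (P7 to P28), and in FB to 0.00704 (DESeq2 size factors), 0.00703 (DESeq2), 0.0852 (covariate) and 0.23 (P7 to P28), with -0.10 (without P1) to 0.0171 (without P14).

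Among named genes, slopes turned within P1 to P7 for Art1 (-0.41) and Hrc (-0.10) in CM, Hrc (-0.22) and Cytl1 (-0.36) in EC and Trbc1 (-0.17) in FB, and within P7 to P28 for Xist in CM (0.12). With the finer name in EC they turned for Xirp2 (-0.0212), Tuba8 (-1.71), Lrtm1 (-0.46) and Hrc (-0.90). With the covariate in FB they turned for Trbc1 (-0.70) and Csrp1 (0.0613), and Inmt in FB ran from -0.12 (without P28) to 2.81 (without P1). Of 1312 named gene values under alternatives, 1128 kept direction and call and 171 lost the call. Of 575 for named exon events 383 kept it and 192 lost it, and of 260 for named differences between types 125 kept it and 135 lost it.

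Differences between types came to 1 gene (CM and EC), 70 (CM and FB) and 3 (EC and FB) without the stage block, and to 1 between EC and FB without P6 and P10. Leaving out stages gave 0 to 147 (without P1), 0 to 2178 (without P1) and 0 to 736 (without P1). Called exon events in CM became 42 unweighted, 212 in cells with at least 10 reads of the gene, 275 away from the shared value and 5 without P6 and P10, with 1 (without P1) to 180 (without P7). In EC they became 1 with the unlogged day, 104, 97 and 1 in the last 3 of these, with 0 (without P1) to 85 (without P7). In FB they became 0 with the unlogged day (limma, 214 unadjusted, no other tool), 31 at a minimum change of 0.20, 82 away from the shared value and 10 without P6 and P10, with 0 (without P1) to 49.

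For the CLIP lists below, the odds ratio and the ratio of the count to the median of random lists of like expression lay on different sides of 1, or the second was 1. In CM these ratios were 0.5 (G3BP1 rising), 0.867 (G3BP1 falling), 0.509 (NCBP2 rising), 0.848 (NCBP2 falling), 0.676 (PTBP1 rising) and 1 (PTBP1 falling). In EC they were 0.870 (G3BP1 rising), 0.75 (G3BP1 falling), 0.846 (NCBP2 rising) and 0.95 (PTBP1 rising), and in FB 0.714, 0.776 and 0.819 (rising, G3BP1, NCBP2 and PTBP1). With DESeq2's calls the odds ratios were 0.735 (G3BP1 CM rising), 0.938 (NCBP2 CM rising), 0.607 (G3BP1 EC falling), 0.832 (NCBP2 EC falling), 0.836 (PTBP1 EC falling), 1.75 (PTBP1 EC rising, now called), 1.32 (G3BP1 FB falling, no longer called) and 1.23 (PTBP1 FB falling, no longer called).

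Within P1 to P7, shares that lost their call or turned were EC (r = -0.403), ER (rho = 0.357, r = 0.393), FB (rho = 0.143, r = 0.0644), GR (r = -0.880), MP (r = 0.125), MyoFB (rho = -0.679, r = -0.763), PC (rho = -0.0714), T (rho = -0.25, r = 0.140) and rMP (rho = 0.857, r = 0.847), by exact permutation. Among all cells rho passed for MP (0.782) and T (0.855). Leaving out stages gave EC r = -0.830 (without P5) to -0.611 (without P1), MP rho = 0.583 (without P10) to 0.867 (without P7) and r = 0.628 (without P28) to 0.827 (without P1). It gave T rho = 0.633 (without P10) to 0.85 (without P5) and r = 0.723 (without P28) to 0.880 (without P5). ER ran from rho = -0.283 (without P3) to 0.2 (without P28) and r = -0.147 to 0.284, and rMP from rho = -0.417 (without P1) to 0.133 (without P10) and r = -0.494 (without P1) to 0.0540 (without P28).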

Other observations

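In this part the levels of T cell markers across types and the correlations of slopes between types were chosen after the data were seen, while the fits of other cell types were planned. Among the immune cells, MP (572 genes rising, 131 falling) and T (539 and 122) changed with age beside CM, EC and FB. In T, 5 of 6 T cell markers and 3 of 19 interferon and MHC genes rose (9 adjusted over the list alone; camera adjusted p with an estimated correlation of 0.0204 and 0.0419). In MyoFB, 8 of 30 extracellular matrix genes rose (18 adjusted over the list alone; adjusted p = 0.0438 with an estimated correlation). The fetal sarcomere list fell in MP (6 of 14, adjusted p = 0.000911 with an estimated correlation), in MyoFB (0.003) and in T (0.00303), and Myh7 fell in MP (slope -1.62 ± 0.19), T (-1.83 ± 0.35), MyoFB (-1.26 ± 0.18), ER (-1.14 ± 0.17), SMC (-0.95 ± 0.18) and PC (-0.88 ± 0.15). Whether RNA of cardiomyocytes in their wells accounts for this was not tested, and 161 MP carry the finer name MP_cm. In SMC the muscle genes Xirp2 (1.84 ± 0.30) and Hrc (1.09) rose, and Igf2 (-1.15) and Gpc3 (-1.66) fell. In GR the neutrophil genes Mmp8 (-2.75 ± 0.42) and Retnlg (-1.15 ± 0.16) fell, over 8 stages. Counts elsewhere were 583 rising and 55 falling in ER, 289 and 29 in MyoFB, 132 and 34 in PC, 72 and 8 in rMP, 38 and 21 in SMC, 6 and 2 in GR, and 1 and 1 in B (9 stages).

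In annotated T cells the 6 T cell markers had a median of 7.01 CPM at P1, 53.8 at P7, 1211 at P10 and 1769 at P28. In FB they went from 0.103 CPM at P1 to 42.2 at P28, and in CM they stood at 19.4 CPM at P10 and 1.95 at P28. In cells annotated ER the genes that rose most steeply included Trbc1, Ccr7, Trbc2 and Cd3d, and the erythroid markers there stood at 16380 CPM at P1, 37920 at P7, 15350 at P10 and 4659 at P28.

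Across 29170 genes, which are not independent replicates, slopes in CM correlated with those in EC at r = 0.340, in CM with FB at 0.243 and in EC with FB at 0.339, while 39 permuted orders of the ages gave up to 0.503, 0.471 and 0.510. Rising in both of a pair were 130 genes (CM and EC), 78 (CM and FB) and 174 (EC and FB), against 5.90, 17.1 and 19.02 for independent lists, and falling in both were 42, 66 and 42. Permuted orders gave up to 442, 396 and 547 genes with a shared direction, more than the real order in each pair. In the real order 3 genes moved in opposite directions, all between CM and FB.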
